A study of Mus musculus with 6 samples.

How the data were processed

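Bulk RNA sequencing measured gene expression in 6 libraries of primary mouse vascular smooth muscle cells from C57BL/6 mice, 3 of control and 3 of Ncor1 knockout cells, grouped by the sample titles and genotype labels. Total RNA was extracted with Trizol and libraries followed a standard Illumina protocol, per the labels' protocols. HISAT2 2.0 and the genome build mm9 are named per the submitters' processing notes. The read counter, the gene annotation, the use of strand and any filter are not given in the sources used here. The count table deposited by the authors holds whole-number counts per gene symbol, not normalized, with 1 column per library. The FPKM table deposited by the authors holds the same genes scaled to gene length and library total. Over 12180 genes, FPKM equalled the count divided by the library total and by 1 gene length, with a relative spread between libraries of at most 1.05e-05, so it holds no separate normalization. Coordinates are not given, since the annotation at hand was of another build, and its table for assembly GRCm38.p6 was used only to list Y chromosome genes by symbol.

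Counts were used as deposited. Of 23349 genes with any count, 13323 passed edgeR's filterByExpr and were tested. TMM factors, robust dispersion estimation and the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 gave log2 fold changes, knockout over control, and p-values, two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. The SE is the log2 fold change divided by the square root of the F statistic. The fit had no replicate term. Gene lists were tested with camera of limma 3.58.1 on log CPM (prior count 2) with a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over 32 lists. These choices, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise. Named genes were the members of the NCOR complex list, of which some values are not reported here; the 8 largest increases and 8 largest decreases among called genes with a mean of at least 5 CPM in the higher group, no overlap between groups and a proper symbol; Acta2, Myh11, Tagln, Cnn1 and Myocd; and from every other list up to 3 called members with the smallest adjusted p where the set test passed, or 1 where it did not. A list of mitochondrially encoded genes matched no symbol as written and was replaced by one with the names the table uses, added after the data were seen.

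Depth was 7125538 to 9579490 counts per library, so 3 counts, the limit that a count of 0 allows, correspond to 0.313 to 0.421 CPM. Exact 95% intervals of ratios were computed from summed counts, conditional on their total, and cover counting error only. Reads shared between near-identical copies could not be assigned here: Gapdh, which has many processed copies, had 265 to 629 counts per library against 30986 to 42058 for Actb. Genes with such copies, class I histocompatibility genes, ribosomal protein genes and overlapping or antisense genes are therefore uncertain. The biological replication is unclear, because the design text names both 3 mice and technical replicates. Counts of library pairs differed by more than sampling noise within groups (chi-square per degree of freedom 1.38 to 1.84), and far more between groups (56.9 to 72.4), so no library was treated as a duplicate. This check cannot tell libraries of separate mice from separate libraries of a shared RNA pool.

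Simulated data had the real library sizes and the trend of the dispersions rather than each gene's own. The pipeline was tested on 12875 of their genes, with 50 changed at each of 4 sizes, equally up and down. It recovered 40% of the genes changed 1.25-fold, 82% at 1.5-fold, 94% at 2-fold and 98% at 4-fold, with 14 false calls (8.19% of calls). Of 40 simulated lists without change the set test called 0, and a raised list was called. Genes were simulated independently of each other, so this does not show how the set test behaves for lists with correlated members. Far fewer genes were changed than the 52.6% called in the real data. These figures therefore do not cover scaling, false calls or the set test where changes are that wide.

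Alternatives were DESeq2 size factors and upper-quartile factors, no filter and at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test with NA values kept, limma-voom, no robust estimation, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with FPKM of at least 1 in 3 libraries and without that filter, each library left out in turn, the replicate number as a block, Y chromosome, Xist and mitochondrial genes left out, and 1 surrogate variable from sva 3.50.0. Fold changes from FPKM are on the log2(value + pseudocount) scale and understate those of low genes. Set tests were repeated with an estimated correlation, with fry, with DESeq2 size factors, without filter, without each library and with the block. Library totals alone and the removal of copy-like symbols (Gm, LOC and pseudogene names) were added after the data were seen.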

Results

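Bulk RNA sequencing was carried out on primary mouse vascular smooth muscle cells, the contractile cells of the arterial wall, from control littermates and from mice carrying a smooth muscle deletion of Ncor1. Ncor1 encodes nuclear receptor corepressor 1, a scaffold that brings histone deacetylase 3 to nuclear receptors and other transcription factors. The cells were exposed to 4-hydroxytamoxifen, which triggers the deletion. There were 6 libraries, 3 of control and 3 of Ncor1 knockout cells. Total counts were 7231968 to 9005690 per control library and 7125538 to 9579490 per knockout library. The first principal component of log CPM held 85.4% of the variance and the second 4.06%. Pearson correlations of log CPM across genes, which are not independent replicates, were 0.992 to 0.993 within and 0.933 to 0.939 between groups, and the biological coefficient of variation was 3.05%. The design text speaks of 3 technical replicates per group, so p-values measure only the spread between these libraries, which may be technical. Values below are TMM-normalised CPM (counts scaled to library size) as mean ± SD with n = 3 per group, and log2 fold changes are knockout over control with the standard error (SE) of the fit. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13323 tested genes, and set tests are camera tests adjusted over the lists.

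The deleted gene was examined first, in every library. Ncor1 stood at 213, 223 and 230 CPM in control replicates 1, 2 and 3 and at 99.3, 93.7 and 94.4 CPM in the knockout replicates. The means were 222 ± 8.79 and 95.8 ± 3.07 CPM, a 2.32-fold lower level in the knockout (log2 fold change -1.21, SE 0.0445, adjusted p = 1.08e-33). The counts are per gene, so reads from exons outside the deleted part are included in the knockout level. How much of that level such reads make up was not tested. Whether cells that kept the gene intact contribute to it was not tested either. Endothelial and macrophage markers were higher in the knockout libraries (median log2 fold changes 1.65 and 3.33). Among the 11 members of the NCOR complex list, 4 were higher, 2 lower and 5 did not pass the test, and the set test gave adjusted p = 0.955. The median of this list was -0.06 and its mean 0.05, with the camera test pointing upward, and with library totals alone the median was 0.08. This median was near 0 and moved with single libraries, to 0.00 without control replicate 1, -0.03 without control replicate 3, 0.01 without knockout replicate 1 and -0.01 without knockout replicate 3. Hdac7, a class II histone deacetylase, was higher (log2 fold change 0.43, SE 0.0394), and so were Tbl1x (0.13), Zbtb33 (0.19) and the low-expressed Coro2a (1.69, SE 0.316, from 1.05 ± 0.231 to 3.42 ± 0.776 CPM). Hdac5 was lower (-0.44, SE 0.0555). Hdac3 (-0.06), Gps2 (-0.06), Tbl1xr1 (-0.07) and Hdac4 (0.01) did not pass the test. The sign of Hdac3, Gps2 and Tbl1xr1 turned with library totals alone, that of Tbl1xr1 also without control or knockout replicate 1, and that of Hdac4 with upper-quartile factors and without control replicate 2. The rise of Zbtb33 lost its call in 3 of the 6 fits that left out a library (without control replicate 1, adjusted p = 0.0621; without control replicate 3, 0.0772; without knockout replicate 2, 0.116) and with the DESeq2 test (0.164), which also ended that of Tbl1x (0.0522).

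**Figure D1:**
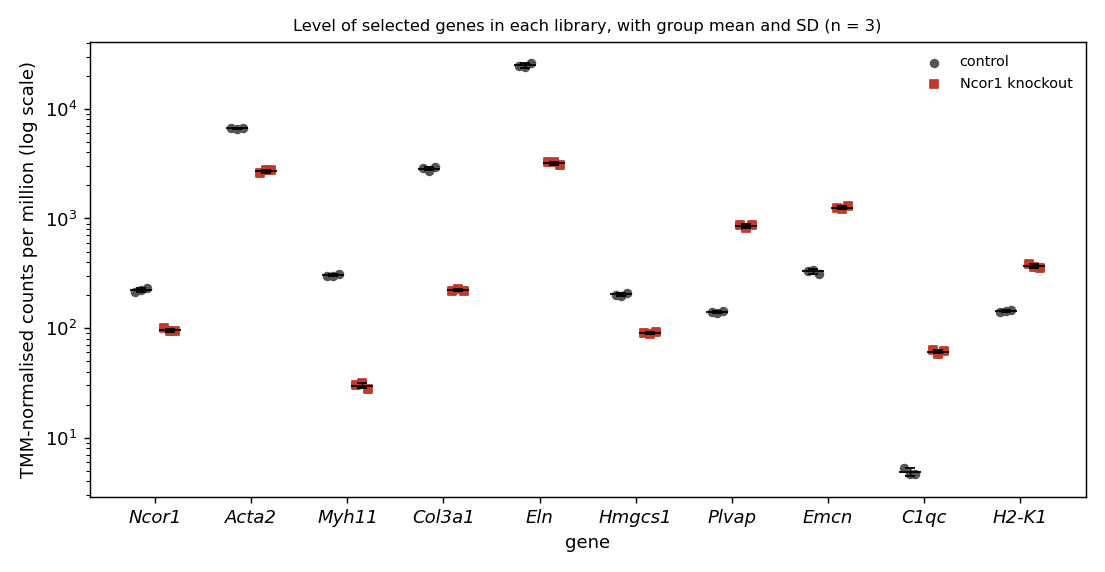
Level of 10 genes in each of the 6 libraries, as TMM-normalised CPM on a log axis, with control libraries as grey circles, knockout libraries as red squares, and black bars for the group mean and SD (n = 3). Ncor1 falls from 222 to 95.8 CPM, Col3a1 from 2854 to 222 CPM and Myh11 from 304 to 29.9 CPM, while Plvap rises from 140 to 859 CPM, and libraries of the different groups do not overlap for any gene shown.

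Expression differed widely between knockout and control cells. At a false discovery rate of 0.05, 3512 genes were higher and 3492 lower in the knockout, together 52.6% of the genes tested. A fold change of at least 2 was reached by 919 of the higher and 817 of the lower genes. In 7703 genes (57.8%) the libraries of the groups did not overlap, against 10% by chance with 3 against 3. Scaling mattered for the balance: TMM factors were 0.948 to 0.961 in control and 1.04 to 1.05 in knockout libraries. With library totals alone the median gene shifted by 0.13 on the log2 scale and 5305 genes were higher and 2405 lower, so 68.8% of calls were higher against 50.1% with TMM. The FPKM values, which are scaled by library totals, gave 4695 higher and 2004 lower genes (70.1% higher). Fold changes below are relative to the TMM scale.

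The 8 largest increases among called genes with a proper symbol and at least 5 CPM in the higher group were as follows. Nxpe5 rose 38.5-fold, Abcg3 36.4-fold, Cd300a 34.2-fold, Wfdc17 29.4-fold, Mmp13 28.6-fold, Lair1 27.2-fold, Mmp12 23.4-fold and Mrc1 23.3-fold by the fitted change. Cd300a and Lair1 are leukocyte inhibitory receptors, Mrc1 is the macrophage mannose receptor, and Mmp12 is macrophage elastase. The 8 largest decreases by the same rule were in Wnt16 (log2 fold change -6.67), a secreted Wnt ligand, the vascular amine oxidase Aoc3 (95.1-fold), the protease Adamts15 (80.6-fold), Lrrc17 (43.3-fold), the BMP family ligand Gdf10 (39.6-fold), Islr (30.6-fold), Wscd2 (30.0-fold) and Rgs4 (28.5-fold), a regulator of G protein signalling. These sizes rest on few counts in the lower group. Wnt16 had 316 counts over the 3 control and 3 counts over the 3 knockout libraries, a ratio of 115 with an exact 95% interval of 39.0 to 561. Adamts15 and Gdf10 had 4 counts each in the knockout, with intervals of 34.1 to 325 and 16.6 to 161, and Nxpe5, Cd300a and Lair1 had 4 each in control, with lower limits of 16.0, 14.2 and 11.3. The intervals cover counting error only.

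Contractile genes were lower in the knockout. Of 28 tested members of the contractile smooth muscle list, 25 were lower, 1 was higher and 2 did not pass, with a median log2 fold change of -1.20 (camera adjusted p = 8.12e-13; adjusted p = 0.122 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain, fell from 304 ± 6.05 to 29.9 ± 1.76 CPM (log2 fold change -3.35, SE 0.0519, adjusted p = 3.69e-54). The integrin subunit Itga8 fell from 269 ± 0.289 to 24.4 ± 1.38 CPM (-3.47, SE 0.0544). Smooth muscle alpha-actin, Acta2, fell less, from 6670 ± 75.2 to 2697 ± 76.1 CPM (-1.31, SE 0.0292), as did transgelin, Tagln, from 3299 ± 33.3 to 942 ± 31.1 CPM (-1.81, SE 0.0308). Calponin, Cnn1, fell by 2.66 on the log2 scale and the transcriptional coactivator Myocd by 1.71. In the same libraries the median of the endothelial list was 1.65 and that of the macrophage list 3.33.

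Among vasoactive receptors and calcium handling genes, 10 of 31 were higher and 19 lower, with a median of -0.42 (camera adjusted p = 0.0345; adjusted p = 0.492 with an estimated correlation). Without control replicate 3 this set test gave adjusted p = 0.0543, and by FPKM with pseudocount 1 the list had 10 higher and 13 lower with a median of -0.11. Rgs5, a pericyte and smooth muscle regulator of G protein signalling, fell from 112 ± 7.38 to 6.17 ± 0.446 CPM (log2 fold change -4.20, SE 0.0891). The lowest value in this list was -4.83, that of Rgs4, among the largest decreases above. Beside Rgs5, both other members with the smallest adjusted p rose and are made mainly by endothelial cells: Edn1, which encodes endothelin-1, 2.82-fold (from 321 ± 11.4 to 904 ± 10.4 CPM) and Nos3, the endothelial nitric oxide synthase, by 1.67 on the log2 scale. Nos3 also belongs to the endothelial list. In the Notch pathway, 5 of 18 members were higher and 11 lower (median -0.46, camera adjusted p = 0.304; the median was -0.22 by FPKM with pseudocount 1), with Notch4, an endothelial Notch receptor, higher by 1.67 (SE 0.0599). Among osteochondrogenic genes, 2 of 14 were higher and 11 lower (median -0.97, camera adjusted p = 7.44e-04; adjusted p = 0.325 with an estimated correlation), and by FPKM without filter the median was -0.18. Within that list Col11a1 fell by 1.92 on the log2 scale and the calcification inhibitor Mgp 2.22-fold, from 1936 ± 75.3 to 871 ± 34.2 CPM, while Bmp4 rose by 0.79. The endothelial and macrophage medians in these libraries were 1.65 and 3.33.

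Genes for extracellular matrix and its assembly were also lower. Of 55 tested members 42 were lower, 6 higher and 7 did not pass (median -1.13, camera adjusted p = 4.28e-13; adjusted p = 0.197 with an estimated correlation). Elastin, Eln, fell from 24920 ± 1123 to 3194 ± 106 CPM (log2 fold change -2.96, SE 0.032, adjusted p = 2.58e-59) and took 2.31% to 2.48% of all counts in control against 0.323% to 0.34% in knockout libraries. Collagen III, Col3a1, fell from 2854 ± 111 to 222 ± 5.29 CPM (-3.68, SE 0.0357, adjusted p = 2.7e-65), and periostin, Postn, from 546 ± 13.3 to 45.5 ± 1.72 CPM (-3.59, SE 0.045). The direction was not shared by decorin, Dcn, a small proteoglycan that also belongs to the fibroblast list, which rose from 26.1 ± 2.61 to 321 ± 7.60 CPM (3.62, SE 0.0545). Matrix proteases and their inhibitors went both ways, 15 of 42 higher and 20 lower (median -0.21, camera adjusted p = 0.247; the median was 0.12 by FPKM with pseudocount 1). The inhibitor Timp3 fell by 1.65 (SE 0.0309). Of the proteases, Mmp12 and Mmp13 were among the largest increases and Adamts15 (-6.33) among the largest decreases. In the TGF-beta list 14 of 37 members were higher and 15 lower (median -0.05, camera adjusted p = 0.87; the median was 0.08 with library totals alone, -0.02 without control replicate 3 and -0.01 without knockout replicate 1), and the ligand Tgfb3 fell from 241 ± 12.5 to 63.0 ± 3.27 CPM (-1.94, SE 0.0486). Beside these matrix lists, the endothelial and macrophage medians were 1.65 and 3.33.

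Markers of other cells of the vessel wall were measured in the same libraries. Of 20 tested endothelial markers 19 were higher and 1 lower (median log2 fold change 1.65, camera adjusted p = 1.17e-12; adjusted p = 0.119 with an estimated correlation). Plvap, a protein of endothelial fenestrae, rose from 140 ± 2.59 to 859 ± 31.5 CPM (2.62, SE 0.038, adjusted p = 1.11e-55). Mmrn2 rose from 152 ± 1.83 to 694 ± 16.2 CPM and endomucin, Emcn, from 329 ± 15.7 to 1253 ± 43.4 CPM, so these transcripts were also measured in the control libraries. The marker that fell was Vwf (-0.57), named here after its value was seen. Of 20 tested macrophage and leukocyte markers 18 were higher, 19 when adjusted over the list alone, and 0 lower by edgeR, as at an unadjusted p under 0.05 (17 higher and 0 lower by the DESeq2 test, 19 and 0 by limma-voom). Without control replicate 1, 19 were higher and 1 lower. The list had a median of 3.33 (camera adjusted p = 9.2e-11; adjusted p = 0.0567 with an estimated correlation), and of 2.05 by FPKM with pseudocount 1. The complement subunits C1qc and C1qb, products of tissue macrophages, rose from 4.89 ± 0.405 to 61.2 ± 2.27 CPM and from 3.47 ± 0.395 to 51.1 ± 4.16 CPM, and the lysosomal protein gene Laptm5 from 3.87 ± 0.486 to 50.2 ± 0.881 CPM.

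Markers of the remaining cell types did not share a direction. Of 13 adventitial fibroblast markers 5 were higher and 6 lower, 7 lower when adjusted over the list alone (median -0.26, camera adjusted p = 0.638; the median was -0.12 with library totals alone and 0.00 by FPKM with pseudocount 1). Of 7 Schwann and neural markers 2 were higher and 5 lower (median -1.20, camera adjusted p = 0.131; the median was -0.58 without the low-count filter, with 2 higher and 8 lower, -0.58 by the DESeq2 test and -0.53 by FPKM with pseudocount 1), with a log2 fold change of -2.13 for the myelin protein gene Pmp22. Of 6 adipocyte markers 3 were higher and 1 lower (median 0.35, camera adjusted p = 0.398), with the lipase Pnpla2 higher by 0.84. The adipocyte count was 2 without control or knockout replicate 2, and the median was -0.37 without the low-count filter. Of 4 mesothelial and epithelial markers 3 were higher, among them keratin 18, Krt18, by 1.64 (SE 0.042). Of the 3 tested skeletal and cardiac muscle markers 0 passed the edgeR test, the DESeq2 test or limma-voom, 1 was lower at an unadjusted p under 0.05, and 1 passed without control or knockout replicate 2. No red blood cell marker was expressed enough to be tested. Transcripts of Y chromosome genes were present in all 6 libraries, and Xist had 0 to 3 counts per library. Of the 4 tested sex-linked genes 1 was lower, Eif2s3y (-0.21, adjusted p = 0.0188), which lost its call with library totals alone (-0.08, adjusted p = 0.425; 2 sex-linked genes were then higher), by FPKM in all 3 fits (adjusted p between 0.249 and 0.297), with the DESeq2 test (adjusted p = 0.158), and without control replicate 3, knockout replicate 2 or knockout replicate 3 (adjusted p = 0.0507, 0.0767 and 0.0743).

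**Figure D2:**
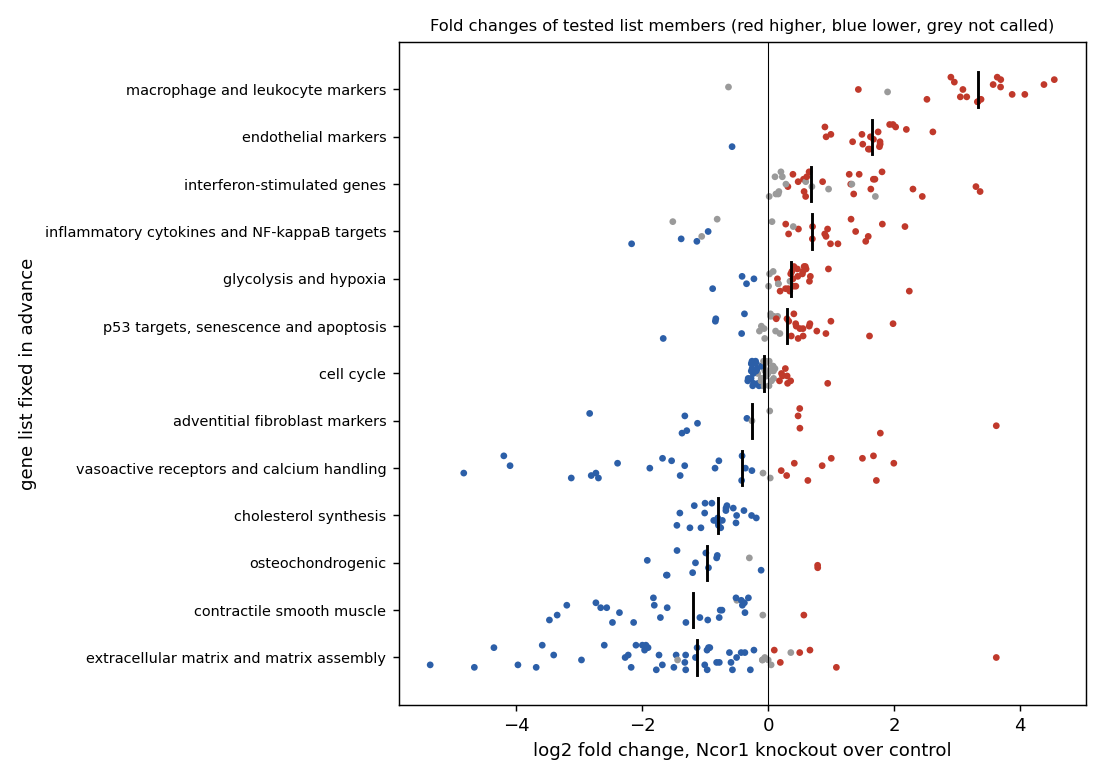
Log2 fold change, knockout over control, of each tested member of 13 gene lists (points; red, called higher; blue, called lower; grey, not called) with the median of each list as a black bar. Macrophage (median 3.33) and endothelial (1.65) markers lie to the right, and contractile (-1.20), extracellular matrix (-1.13) and cholesterol synthesis (-0.79) genes to the left.

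Genes of cholesterol synthesis fell together. All 23 tested members were lower in the knockout (median log2 fold change -0.79, camera adjusted p = 8.11e-10; adjusted p = 0.197 with an estimated correlation), and 21 were with library totals alone. Squalene epoxidase, Sqle, fell from 157 ± 4.21 to 56.9 ± 5.78 CPM (-1.45, SE 0.0541, adjusted p = 1.53e-32), Cyp51 from 157 ± 6.81 to 66.4 ± 4.06 CPM (-1.24, SE 0.0512), and the HMG-CoA synthase gene Hmgcs1 from 203 ± 6.17 to 90.0 ± 1.54 CPM (-1.17, SE 0.0448). The endothelial and macrophage medians in these libraries were 1.65 and 3.33.

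Nuclear receptors recruit NCOR1, so lists of their targets were included. LXR targets had 7 of 15 members higher and 3 lower (median 0.04, camera adjusted p = 0.419; the median was 0.18 with library totals alone, 0.10 without control replicate 3, and 0.07 and 0.11 without knockout replicates 2 and 3), and apolipoprotein E, Apoe, rose from 141 ± 10.2 to 367 ± 17.6 CPM (log2 fold change 1.38, SE 0.0429). PPAR targets had 10 of 27 higher and 10 lower (median 0.02, camera adjusted p = 0.896), against 14 higher and 9 lower with library totals alone (median 0.16; the median on the TMM scale was 0.08 and 0.06 without control replicates 2 and 3, and 0.07, 0.01 and 0.04 without knockout replicates 1, 2 and 3), and Angptl4, an inhibitor of lipoprotein lipase, rose from 35.4 ± 1.93 to 208 ± 1.91 CPM (2.56, SE 0.0535). Thyroid hormone receptor targets had 2 of 9 higher and 7 lower (median -0.57, camera adjusted p = 0.0385; adjusted p = 0.301 with an estimated correlation). The members lower in that list include the receptor itself, Thra (-1.21, SE 0.082), and the calcium pump Atp2a2 (-0.41, SE 0.0333), while the amino acid and thyroid hormone transporter Slc16a10 was higher (1.87, SE 0.141). The thyroid set test lost its call with the replicate number as a block (adjusted p = 0.0567), without control replicate 1 (adjusted p = 0.0615) and without control replicate 3 (0.0541), and the median was -0.28 by FPKM with pseudocount 1. The endothelial and macrophage medians in the same libraries were 1.65 and 3.33. Retinoic acid receptor targets had 4 of 14 higher, 5 when adjusted over the list alone, and 8 lower (median -0.43, camera adjusted p = 0.245; the median was -0.25 without the low-count filter and by the DESeq2 test and -0.01 by FPKM without filter), and the retinaldehyde reductase Dhrs3 fell from 61.8 ± 2.94 to 8.36 ± 0.835 CPM. Glucocorticoid and mineralocorticoid receptor targets had 6 of 16 higher and 6 lower (median -0.26, camera adjusted p = 0.896; the median was -0.10 without control replicate 2, -0.12 with library totals alone and -0.02 by FPKM without filter), with Errfi1 higher by 1.24. The ERR and mitochondrial biogenesis list had 3 of 15 higher and 3 lower (median 0.03, camera adjusted p = 0.937), against 6 higher and 1 lower with library totals alone (median 0.17). Esrra was higher by 0.38, and without control replicate 1 only 3 members passed. Without control replicate 2 this list had 5 lower members, and without knockout replicate 2 its median was 0.02 with 1 lower. Circadian clock genes had 4 of 13 higher and 3 lower (median -0.03, mean 0.06, camera upward with adjusted p = 0.955; the median was 0.10 with library totals alone, 0.03, -0.01 and -0.05 without control replicates 1, 2 and 3, and -0.05 and 0.07 without knockout replicates 1 and 3), with the repressor Nr1d1 higher by 0.95 (SE 0.0683).

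Inflammatory and interferon genes were mostly higher. Of 25 cytokine and NF-kappaB target genes 16 were higher and 4 lower (median 0.70, camera adjusted p = 0.00862; adjusted p = 0.532 with an estimated correlation). By FPKM without filter the median was 0.39. Control replicate 2 stood near the knockout libraries for this list: the mean deviations of its members on the log2 scale were -0.46, 0.12 and -0.27 in control replicates 1, 2 and 3 and 0.18, 0.21 and 0.22 in the knockout replicates. The adhesion molecule Icam1 rose from 153 ± 9.42 to 537 ± 5.05 CPM (log2 fold change 1.81, SE 0.039) and cyclooxygenase 2, Ptgs2, from 197 ± 3.05 to 516 ± 25.3 CPM (1.39, SE 0.0379), whereas the chemokine Cxcl12 fell from 4195 ± 36.6 to 2168 ± 65.7 CPM (-0.95, SE 0.0294). Of 34 interferon-stimulated genes 21 were higher and 0 lower by edgeR, against 25 and 0 at an unadjusted p under 0.05 and by both the DESeq2 test and limma-voom (median 0.67, camera adjusted p = 9.51e-07; adjusted p = 0.492 with an estimated correlation). Without knockout replicate 1, 23 were higher and 1 lower. The antigen presentation genes H2-K1, H2-D1 and B2m rose by 1.36, 1.31 and 0.60. H2-K1 and H2-D1 are similar in sequence to other class I genes, so reads may be split among them and their levels are uncertain. Macrophage and endothelial markers, both of which can express such genes, were higher in the same libraries (medians 3.33 and 1.65). Of 26 AP-1 and immediate early genes 15 were higher and 7 lower (median 0.32), against 16 and 3 with library totals alone. The members with the smallest adjusted p were Maff (1.04), the MAP kinase phosphatase Dusp6 (1.34, SE 0.0664) and Ier3 (1.04). The camera test of this list (adjusted p = 0.0403) was lost with an estimated correlation (adjusted p = 0.325), with the replicate number as a block (0.0567) and in all 6 fits that left out a library (adjusted p between 0.0519 and 0.0864). Its median was 0.15 without control replicate 1, 0.21 without control replicate 3 and 0.20 without knockout replicate 1, and without control replicate 2 it had 4 lower members.

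Of 50 cell cycle genes 8 were higher and 18 lower (median -0.07, camera adjusted p = 0.352), a balance that turned with library totals alone (15 higher, 5 lower, median 0.06), and cyclin D1, Ccnd1, rose from 488 ± 5.38 to 940 ± 19.0 CPM (log2 fold change 0.95, SE 0.0323). Of 32 glycolysis and hypoxia genes 22 were higher, 24 when adjusted over the list alone, and 4 lower (median 0.37, camera adjusted p = 2.01e-04; adjusted p = 0.37 with an estimated correlation). Adrenomedullin, Adm, rose from 52.2 ± 3.23 to 246 ± 6.58 CPM (2.24, SE 0.0494), and the glycolytic enzymes Hk1 and Pkm rose by 0.57 and 0.44. Of 33 genes of p53 response, senescence and apoptosis 18 were higher and 5 lower, 19 and 6 when adjusted over the list alone (median 0.30, camera adjusted p = 0.00567; adjusted p = 0.178 with an estimated correlation). Among them Mdm2, which targets p53 for degradation, rose from 112 ± 7.11 to 225 ± 4.65 CPM (1.00, SE 0.0441), the apoptosis gene Pmaip1 rose by 1.98 and Igfbp3 by 1.61. Endothelial and macrophage markers were higher in the same libraries as the glycolysis and p53 lists (medians 1.65 and 3.33). Unfolded protein and integrated stress response genes had 9 of 34 higher, 10 when adjusted over the list alone, and 19 lower (median -0.18, camera adjusted p = 0.0631), a balance lost with library totals alone (12 higher, 12 lower, median -0.05) and by FPKM (11 and 11). The stress regulator gene Nupr1 had a log2 fold change of -1.43. Without the low-count filter this set test passed (adjusted p = 0.0205). Oxidative stress and NRF2 targets had 15 of 34 higher, 17 when adjusted over the list alone, and 9 lower (median 0.12, camera adjusted p = 0.247), against 20 higher and 5 lower with library totals alone. The extracellular superoxide dismutase gene Sod3 had a log2 fold change of -1.78.

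Of 77 oxidative phosphorylation genes 16 were higher and 11 lower, 12 and 9 when adjusted over the list alone (median 0.04, camera adjusted p = 0.488; the median was 0.06 without knockout replicate 1), whereas 44 were higher and 3 lower with library totals alone. The smallest adjusted p in that list was that of Cox4i2, an alternative subunit of cytochrome oxidase, with a log2 fold change of -2.52 (SE 0.183). Of 72 cytoplasmic ribosomal protein genes 32 were higher and 4 lower (median 0.10, camera adjusted p = 0.0199; adjusted p = 0.37 with an estimated correlation), and 56 were higher with library totals alone (median 0.23). The endothelial and macrophage medians were 1.65 and 3.33 in the same libraries. Rps27a, Rplp2 and Rpl29 were higher by 0.72, 0.33 and 0.28. Many processed copies of ribosomal protein genes exist in the genome and share reads with them, so these levels are uncertain. Of 9 histone genes tested 1 was higher and 6 lower (median -0.34, camera adjusted p = 0.128), with a log2 fold change of -0.73 for the linker histone Hist1h1c. Without control replicate 3 only 4 histone genes passed, without knockout replicate 1 the median was -0.52, and the median was -0.20 with library totals alone, -0.09 without the low-count filter, -0.12 by the DESeq2 test and 0.01 by FPKM without filter. For every list described here and fixed before the data were examined whose count adjusted over the list alone is not given, that adjustment left the counts of higher and lower members as over all genes.

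Of the 32 lists with at least 5 tested members, 14 passed the camera test with its preset correlation and none with the estimated correlation, where the lowest adjusted p was 0.0567. The preset test also passed 5 to 10 lists under the other 9 ways to divide the 6 libraries into groups of 3. Each of these mixes control and knockout libraries unequally, so it still holds part of the group difference. These calls are therefore not a rate of false calls.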

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

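Library totals alone and the removal of copy-like symbols were chosen after seeing the data; the other settings were planned. The log2 fold change of Ncor1 stayed between -1.25 and -1.01 over 21 alternatives and kept its call in all of them. Library totals alone gave 5305 higher and 2405 lower genes and kept 84.5% of the calls, and 87 of the called genes had the opposite sign. The FPKM fits, also scaled by totals, gave fewer lower genes: 2004 with pseudocount 1, 1987 with pseudocount 0.1 and 2130 without filter, and 364, 544 and 366 of them at least 2-fold lower. Library totals alone also gave fewer genes at least 2-fold lower, 672 against 817 with TMM. Between the 2 FPKM fits with the same filter, the larger pseudocount lowered that count from 544 to 364. The rest of the cause was not tested. In the other settings all 4 counts stayed within 1.5 times; leaving out a library gave 3224 to 3381 higher and 3186 to 3342 lower genes, and DESeq2's test gave 2785 and 2639, with 74.0% of the calls kept.

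The libraries of the groups share only a number: correlations of same-numbered libraries' deviations from their group means were 0.00398 to 0.0232. Those of differently numbered libraries from different groups were -0.0239 to 0.00664. Of the 6 libraries 5 correlated best with their own number. The deviations sum to 0 within each group, so these matches are not independent, and values this near 0 do not show a pairing by number. With the replicate block 3509 genes were higher and 3486 lower. The block ended the set calls of AP-1 genes and thyroid hormone receptor targets (both adjusted p = 0.0567) and no other set call; the cause was not tested.

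With an estimated correlation each of the 14 set calls was lost (the cause was not tested): contractile 0.122, extracellular matrix 0.197, inflammatory 0.532, interferon 0.492, AP-1 0.325, thyroid 0.301, cholesterol 0.197, ribosomal 0.37, glycolysis 0.37, p53 0.178, osteochondrogenic 0.325, vasoactive 0.492, endothelial 0.119 and macrophage 0.0567 (adjusted p). Fry, which tests whether a list moves on balance one way and does not compare it with other genes, called further lists: proteases 6.38e-05, TGF-beta 0.0268, LXR 0.0374, PPAR 6.28e-04, retinoic acid 8.94e-04, histones 0.00916, stress response 2.5e-04, NRF2 0.00195, adipocyte 0.00529 and Schwann 0.00166. For fibroblast markers fry pointed upward (0.0458) where camera pointed downward; the cause was not tested. Without the filter the stress response list passed camera (0.0205); the cause was not tested. Leaving out a library gave adjusted p of 0.0519 to 0.0864 for AP-1, 0.0303 to 0.0615 for thyroid and 0.0239 to 0.0543 for vasoactive genes, with fewer samples in each fit. Of 1906 values for 91 genes under the naming rule none changed direction with a call and 13 lost their call. Those belong to Eif2s3y, Zbtb33 and Tbl1x (DESeq2, adjusted p = 0.0522). Low depth limits genes under about 0.421 CPM, where 3 counts or fewer are seen in the shallowest library.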

Other observations

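The tests in this part, 6 further gene groups (adjusted over these 6) and the genes named from them were chosen after the data were seen, while the lists of markers, cholesterol synthesis and interferon genes were fixed before. Members of the Wnt pathway were mostly lower, 29 of 49 against 6 higher (median log2 fold change -0.58, camera adjusted p = 8.44e-05; adjusted p = 0.0875 with an estimated correlation). The secreted Wnt modulators Sfrp2 and Dkk3 fell from 1817 to 297 CPM and from 416 to 65.2 CPM, and the matricellular target Wisp2 from 1472 to 353 CPM, while Sfrp1 rose from 466 to 1151 CPM. In the PDGF and IGF axis 13 of 19 members were lower and 3 higher (median -0.73, camera adjusted p = 0.00107; adjusted p = 0.178 with an estimated correlation). Igfbp2 fell from 1753 to 231 CPM and Pdgfrb, the PDGF receptor of mural cells, from 729 to 207 CPM. Pdgfb, a ligand made by endothelial cells, rose from 56.0 to 123 CPM. In the libraries where these lists were lower the endothelial and macrophage medians were 1.65 and 3.33.

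VEGF, angiopoietin and FGF ligands and receptors had 16 of 30 members higher and 9 lower (median 0.25, camera adjusted p = 0.0363; adjusted p = 0.178 with an estimated correlation). Esm1, counted in this list though not itself such a ligand or receptor, rose from 154 to 951 CPM. The phosphate hormone gene Fgf23 rose from 6.26 to 51.8 CPM and Flt4 from 13.5 to 64.4 CPM, and Fgfr2 fell from 206 to 45.6 CPM. The VEGF list shares 4 members with the endothelial markers, and without these 12 of 26 were higher and 9 lower (median 0.19). Complement genes had 10 of 17 higher and 5 lower (median 1.16, camera adjusted p = 0.0176; adjusted p = 0.276 with an estimated correlation): C3 rose from 20.5 to 91.5 CPM and C4b fell from 49.0 to 6.49 CPM. The C1q subunits, 3 of these genes, are macrophage markers and rose with that list (median 3.33), and without them 7 of 14 were higher and 5 lower (median 0.38). Guidance genes of the semaphorin, slit, netrin and ephrin families had 18 of 43 higher and 22 lower (median -0.15, camera adjusted p = 0.431), with Slit3 going from 15.4 to 0.832 CPM and Sema6b from 9.04 to 42.2 CPM. Of 13 mitochondrially encoded genes 10 were lower, by little (median -0.13, camera adjusted p = 0.0176; adjusted p = 0.35 with an estimated correlation), a size like the shift between TMM and library totals (0.13).

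Endothelial and macrophage markers were higher while contractile and matrix genes were lower. A passive loss of smooth muscle cells would raise alike those markers of other cells that smooth muscle cells do not make. The macrophage median exceeded the endothelial one by 1.68, with middle ranges of 2.94 to 3.69 and 1.45 to 1.82. Fibroblast markers had a median of -0.26, with members from -2.83 to 3.62. Unequal medians alone do not settle this, since which of these markers smooth muscle cells make is not known here. More endothelial cells and macrophages in the knockout cultures cannot be told apart from higher expression in the same number of such cells, since the 37 of 40 markers that were higher only restate the pattern; abundant ones include Cdh5 (467 to 1427 CPM), Pecam1 (432 to 1303 CPM) and Lyz2 (31.7 to 279 CPM). Of the endothelial markers 7 stand in another list as well, added ones included, and of the macrophage markers 3; in control 20 of 20 endothelial and 13 of 20 macrophage markers had at least 1 CPM. Whether expression also changed within the smooth muscle cells cannot be told apart in bulk RNA: Acta2 and Myh11 fell by amounts that differ by 2.04 (SE 0.0595), but other cells can make part of such transcripts.

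All 23 tested cholesterol synthesis genes were lower. Scaling does not account for this, since at least 19 were lower under every scaling tried, including totals and FPKM. Nor do expression level and transcript length, since the lowest median among 10000 random lists matched on both was -0.45 against -0.79 observed. A different mix of cells and a response to the Ncor1 deletion cannot be told apart: the median lay 0.41 above that of the contractile list, and all cell types make these transcripts, so the fall may come from either.

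Interferon-stimulated genes were higher in the knockout but varied among the libraries of both groups. Their mean deviations on the log2 scale were 0.82, 0.46 and 0.22 in knockout replicates 1, 2 and 3. The values in control replicates 1, 2 and 3 were -0.35, -0.50 and -0.65, the same order by replicate number. With that number as a block 28 members were higher and 0 lower (median 0.71), against 21 and 0 without it. Knockout replicate 1 alone does not carry the difference, since without it 23 members were higher and 1 lower with a median of 0.56, against 21, 0 and 0.67 with all libraries. Transcripts of additional macrophages or endothelial cells cannot be told apart from a change in the smooth muscle cells; the list's median differed from that of the endothelial list by -0.98, and the levels of its members in each cell type are not known here.

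The 6 libraries can be divided into groups of 3 in 10 ways, too few for a share under 0.05. The real grouping called 3512 genes in its larger direction, and 919 with at least a 2-fold change, and the highest of the other groupings called 0 in both cases, so 1 of 10 reached the real value. Every other grouping has control and knockout libraries on both sides. The group difference then widens the spread within its groups and leaves few calls possible, so these 0 counts do not speak to chance. For gene lists the real grouping called 14 and the highest other 10, again with 1 of 10 reaching the real value. The other groupings mix the libraries unequally and keep part of the group difference, so their list calls need not be false. The libraries of a group may also be technical replicates, so no grouping speaks to other differences between the cultures.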
